A study of Mus musculus with 8 samples.

How the data were processed

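RNA from 8 samples was measured on one-colour Cy3 arrays of an Agilent design with probes for mouse long non-coding RNAs and mRNAs. The labels describe 6 cultures of aortic smooth muscle cells at passage 3, all transduced with adenovirus at a multiplicity of infection of 100 and harvested 3 days later, and 2 wild-type tissues. The cultures form 3 groups of 2 arrays, namely wild-type cells with an empty adenovirus, Srf knockout cells with the same empty virus, and wild-type cells with a Myocd adenovirus. Aorta and liver have 1 array each. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

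Per the file headers, the authors read each array with Agilent Feature Extraction 11.0.1.1, which gives a processed intensity per spot. The 75th percentiles of this intensity differ between the arrays, so it was scaled here. The submitters' processing notes name the same software and version. The authors also deposited a table of log2 values for 42995 probes, all of them well above background on 4 or more of the 8 arrays. Its columns follow the scanner values of the same arrays in the same direction (Pearson's r across probes from 0.997 to 1.00) and have nearly the same distribution, with medians of 7.27, 7.27, 7.27, 7.27, 7.27, 7.27, 7.21 and 7.16. The normalization behind this table is not given in the sources used here, and its values served only as an alternative.

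Each array held 61500 spots outside the control classes, for 60930 probes, of which 30 had 20 spots each. Outlier-flagged spots were left out and spots of one probe were averaged on the log2 scale. A level is the log2 processed intensity minus the array's own 75th percentile. A probe was tested if it was well above background on every array of at least 1 cultured group, which kept 44081 probes. Group means were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over all 6 cultured arrays with 3 residual degrees of freedom, two-sided, and a call needed a Benjamini-Hochberg adjusted p under 0.05. SE is limma's standard error of the log2 change, from a fit that assumes the same spread in all cultured groups. Where a probe was not well above background on any array of a group, its fold is a lower bound, computed from the bright group's mean and, on each dim array, the higher of the probe's own value and the lowest value among probes well above background. No spot was saturated. The number of arrays limits the precision, and no error can be given for the single aorta and liver arrays. The 2 tissues were compared with each other, and aorta with the wild-type cells, by counting probes at least 4-fold apart, bounds included.

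Names came from the RefSeq accessions of 15 probes, each with 20 spots, and all 15 accessions matched a mouse gene in a table built on GRCm38. The array files carry an mm9 design, so no coordinates are given. Control spots name the 5′ and 3′ ends of mouse Gapdh and Pgk1. All other probes carry only the maker's identifier. No probe was assigned to Srf or Myocd here, so the sample labels were not checked against either target. Of the 22 gene lists fixed before the data were examined, none had 5 identified members, and the planned list tests were not run. Also before the data were examined, the rule for named genes asked for Srf, Myocd and the largest changes among probes with a gene symbol that were measured in both groups. With 15 symbols, all of these genes were reported instead, a choice made after the files were seen. For other probes, the rule was applied to identifiers, at most 2 per direction and comparison.

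Probe sets defined after the data were seen were tested with camera (preset and estimated correlation) and fry in limma, in a family of 12 tests. They were 4 classes of identifier (mouselincRNA, humanlincRNA, MM9LINCRNAEXON and ASMM10UP) and the probes at least 4-fold apart between aorta and liver in either direction. Counts of calls in the 4 classes were also set against 10000 lists of tested probes matched in 50 bins of mean level, as two-sided permutation p-values adjusted over 16 values. A Fisher test without matching was run on these counts first and set aside, because humanlincRNA and mouselincRNA probes were dim, with median wild-type levels of -3.43 and -3.62 against -1.53 for ASMM10P. Overlaps between the contrasts were compared with independent lists and with 100 simulations of unchanged groups that share the wild-type arrays.

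The wild-type and knockout arrays lay on slide 1, and the Myocd, aorta and liver arrays on slide 2. The knockout contrast and aorta against liver each lie within 1 slide. Slide and Myocd cannot be told apart in the design, so a fit with slide as a block was not possible. In 20 simulated sets built from the real levels and spread, 200 of 43985 probes were changed. The adjustment was therefore stricter than in the data, where more probes were called, and these shares do not give the recovery in the data. In these sets, 54.0% of probes changed 4-fold in the knockout contrast were called, and 0.224% of those changed 2-fold. For the Myocd contrast these shares were 54.1% and 0.0746%. False calls were 5.03% and 5.30% of all calls. The sets drew independent noise with the same spread in all groups, so this does not give the share of false calls in the data.

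Alternatives were quantile normalization, centring on the median of bright probes, normexp with an offset of 50, the authors' log2 values, other filters on dim probes, only the groups compared, eBayes with trend and robust settings, the replicate number as a block, an added 2-fold threshold, and leaving out each array. The files hold no mean spot signal, so normexp used the median spot and median background signals. Array weights, a crossed replicate block and the tests of sets and of identifier classes were added after the data were seen.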

Results

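Expression was profiled in mouse aortic smooth muscle cells, the contractile cells of the vessel wall, after loss of Srf or gain of Myocd. Srf encodes serum response factor, a transcription factor that binds CArG elements in many cytoskeletal and smooth muscle genes, and Myocd encodes myocardin, its coactivator in smooth and cardiac muscle. The design asks which long non-coding RNAs and mRNAs depend on Srf, which respond to Myocd, and how these transcripts lie in whole aorta and liver. There were 2 arrays each of wild-type cells with empty adenovirus, Srf knockout cells with empty adenovirus and wild-type cells with Myocd adenovirus, and 1 array each of aorta and liver. The 75th percentile of the processed intensity was 452 to 498 on the 6 cultured arrays, 364 in aorta and 165 in liver. The share of probes well above background was 68.2% to 74.7% in cultured cells, 68.9% in aorta and 62.2% in liver. The probe-wise log2 differences between replicates had a robust SD of 0.40 for wild-type, 0.20 for knockout and 0.20 for Myocd arrays, and the spread of repeated spots within an array would give 0.093, 0.073 and 0.076.

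In Srf knockout cells, Tfrc, the transferrin receptor that brings iron into cells, fell 2.34-fold against wild-type cells. Its level was 5.14 ± 0.0058 in knockout and 6.36 ± 0.41 in wild-type cells (SD, n = 2 each), a log2 change of -1.22 (SE 0.21, limma adjusted p = 0.0126). G6pd2, an autosomal retrocopy of the glucose-6-phosphate dehydrogenase gene, rose 1.82-fold, from 4.14 ± 0.11 to 5.01 ± 0.08, a log2 change of 0.87 (SE 0.14, limma adjusted p = 0.0111). G6pd2 shares sequence with its X-linked parent gene, so the probe's transcript is uncertain. The other 13 identified genes did not pass, and the same 2 passed when adjusted over the list alone, a list not fixed in advance. Actb, the cytoplasmic actin gene and a known target of serum response factor, had a log2 change of -0.47 (SE 0.18, limma adjusted p = 0.127), and without wild-type replicate 1 it passed at -0.67 (limma adjusted p = 0.0410). Rpl13a, a ribosomal protein gene, stood at -0.54 (limma adjusted p = 0.0743) and passed without wild-type replicate 1 (limma adjusted p = 0.0370), with quantile normalization (limma adjusted p = 0.0222) and with normexp (limma adjusted p = 0.0243). Normexp also added Hsp90ab1 (limma adjusted p = 0.0342) and Nono, an RNA-binding protein gene (limma adjusted p = 0.0383), both lower, and Ldhal6b passed as higher among probes well above background on all 6 arrays (limma adjusted p = 0.0497). Values near 0 were found for the tubulin gene Tuba1b (0.02), the cyclophilin gene Ppia (-0.04), the glycerol kinase gene Gk (0.01) and B2m (0.01), the light chain of MHC class I, and the signs of all 4 depended on the scaling or on single arrays. Both calls needed both knockout arrays, although the changes stayed about as large. Without knockout replicate 1 or 2, the log2 change was -1.23 or -1.22 for Tfrc and 0.81 or 0.92 for G6pd2, and limma's adjusted p became 0.0862 or 0.0716 for Tfrc and 0.102 or 0.0638 for G6pd2. Both passed in the other 14 of 16 alternatives. The fit of only the groups compared and the fits without either Myocd array are the same fit here, so this tally counts it more than once.

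The knockout contrast called 9096 of 44081 tested probes (20.6%, limma), of which 5395 were higher and 3701 lower in knockout cells. This excess of rises depended on the scaling, with 4943 higher and 4625 lower probes under quantile normalization and 4702 and 4537 with the authors' log2 values. Changes of at least 4-fold were found for 1153 of the higher and 320 of the lower probes. The largest rises measured in both groups were those of ASMM10P049587, by 7.53 on the log2 scale (SE 0.35, limma adjusted p = 0.00016), and ASMM10P012699, by 7.49 (SE 0.28, limma adjusted p = 9.45e-05). The first of these was also high in aorta, at 7.83 against -0.75 in liver, while the second stood at -2.83 against -1.01. The largest falls were those of ASMM10P053818, at -7.55 (SE 0.22, limma adjusted p = 7.07e-05), and ASMM10P006969, at -7.17 (SE 0.16, limma adjusted p = 4e-05). ASMM10P053818 stood at 7.77 in aorta and 10.02 in liver. Of the higher probes, 734 were not well above background on either wild-type array, with bounds of up to at least 326-fold. Of the lower probes, 182 were not well above background on either knockout array, with bounds of up to at least 32.1-fold. The count was 2701 without knockout replicate 1 and 3789 without replicate 2, where the lone knockout array was assumed to vary like the other groups. Wild-type and knockout arrays shared a slide, and a fit of these 4 arrays alone called 6443 probes.

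Probes whose identifiers begin with humanlincRNA or mouselincRNA were called less often in the knockout contrast than other probes of the same level, with the 75th percentile scaling, and matched lists were not drawn for other scalings. Of 436 tested humanlincRNA probes, 31 rose and 2 fell, where level-matched lists held on average 53.4 rising and 23.9 falling probes (permutation test, adjusted p = 0.0016 and 0.00107). Of 288 mouselincRNA probes, 20 rose and 3 fell, against 37.8 and 15.2 in matched lists (permutation test, adjusted p = 0.0016 and 0.0016). ASMM10UP probes rose in 18 of 379 cases, against 46.5 in matched lists (permutation test, adjusted p = 0.00107), and 18 fell, against 25.0 (permutation test, adjusted p = 0.208). For the 51 MM9LINCRNAEXON probes, 7 rose and 2 fell, and neither number differed from matched lists (permutation test, adjusted p = 0.851 and 0.956). These permutation tests draw probes as independent units, so their p-values leave out correlation between probes and are too small where it exists. The estimated correlation was 0.025 among humanlincRNA and 0.021 among mouselincRNA probes. As a set, the humanlincRNA probes had a median log2 change of 0.24 but did not pass camera (limma adjusted p = 0.0509, and adjusted p = 0.639 with an estimated correlation), and neither did the other 3 classes. With fry its limma adjusted p was 0.0916. Under camera it passed without knockout replicate 1 (limma adjusted p = 0.0383), Myocd replicate 1 (limma adjusted p = 0.0257) or Myocd replicate 2 (limma adjusted p = 0.0357). With quantile normalization, 21 humanlincRNA probes rose and 8 fell, and 10 mouselincRNA probes rose and 6 fell. With the authors' log2 values these numbers were 17 and 7, and 8 and 3, and normexp gave 18 humanlincRNA and 7 mouselincRNA calls. Array weights gave 13 humanlincRNA and 12 mouselincRNA calls. No filter on dim probes gave 26 and 10, and probes well above background on all 6 arrays gave 25 and 12. The 33 humanlincRNA calls became 4 without knockout replicate 1, 3 without knockout replicate 2 and 61 without wild-type replicate 1. The 23 mouselincRNA calls became 7 without either knockout array, 40 without wild-type replicate 2 and 13 without either Myocd array. The 36 ASMM10UP calls became 7 without knockout replicate 1, 16 without replicate 2 and 72 without wild-type replicate 2.

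With Myocd adenovirus, G6pd2 fell 3.17-fold against empty adenovirus, from 4.14 ± 0.11 to 2.48 ± 0.06 (SD, n = 2 each), a log2 change of -1.67 (SE 0.14, limma adjusted p = 0.00152). Hsp90ab1, a constitutive cytosolic chaperone gene, fell 1.61-fold (log2 change -0.69, SE 0.14, limma adjusted p = 0.0272), and Rpl13a fell 1.65-fold (log2 change -0.72, SE 0.17, limma adjusted p = 0.0410). Gk, which encodes glycerol kinase, rose 1.60-fold (log2 change 0.68, SE 0.15, limma adjusted p = 0.0331), and Ldhal6b, a lactate dehydrogenase-like gene, rose 1.52-fold (log2 change 0.60, SE 0.14, limma adjusted p = 0.0420). The other 10 identified genes did not pass. Adjusted over the list alone, Gusb, the lysosomal beta-glucuronidase gene, passed as a sixth gene, at -0.55. Over all probes, Gusb passed with normexp (limma adjusted p = 0.0164), with trend and robust settings (limma adjusted p = 0.0363) and among probes well above background on all 6 arrays (limma adjusted p = 0.0444), and Nono passed with normexp (limma adjusted p = 0.0280). Actb stood at 0.26 (SE 0.18, limma adjusted p = 0.387), and Tfrc at 0.33 (SE 0.21, limma adjusted p = 0.357). Without wild-type replicate 2, Tfrc passed at 0.62 (limma adjusted p = 0.0372). G6pd2 kept its call without any single array, with limma adjusted p values of up to 0.0201. The calls of Hsp90ab1, Rpl13a, Gk and Ldhal6b were lost without either knockout array, with limma adjusted p values of 0.0753, 0.0946, 0.0823 and 0.0978. Their log2 changes stayed at -0.69, -0.72, 0.68 and 0.60, since the knockout arrays enter this contrast only through the estimate of the spread. Without Myocd replicate 1 or 2, changes of the same direction remained for all 4 genes, from 0.57 for Ldhal6b to 0.80 in size for Rpl13a. Without Myocd replicate 1 their limma adjusted p values were 0.122, 0.128, 0.139 and 0.159, and without replicate 2 they were 0.164, 0.214, 0.181 and 0.215. Gk was also lost without wild-type replicate 1 (limma adjusted p = 0.0598), and Rpl13a and Ldhal6b without wild-type replicate 2 (limma adjusted p = 0.0633 and 0.0628). With quantile normalization, Hsp90ab1 did not pass (limma adjusted p = 0.0904), and with normexp, Ldhal6b did not (limma adjusted p = 0.154). Over all 15 alternatives, G6pd2 passed in 15, Hsp90ab1, Rpl13a and Gk in 6 each and Ldhal6b in 4. The fit of only the groups compared and the fits without either knockout array are the same fit here, so these tallies count it more than once. Slide is confounded with Myocd in these calls, since the Myocd arrays lay on slide 2 with both tissues. Against wild-type cells, aorta stood at -1.89 log2 units for G6pd2, -1.84 for Hsp90ab1, -2.88 for Rpl13a, 2.83 for Gk and 0.91 for Ldhal6b. Liver lay on the same side of wild-type cells for each of these genes. A slide effect or a tissue difference would give this, so slide is not excluded for these calls.

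**Figure D1:**
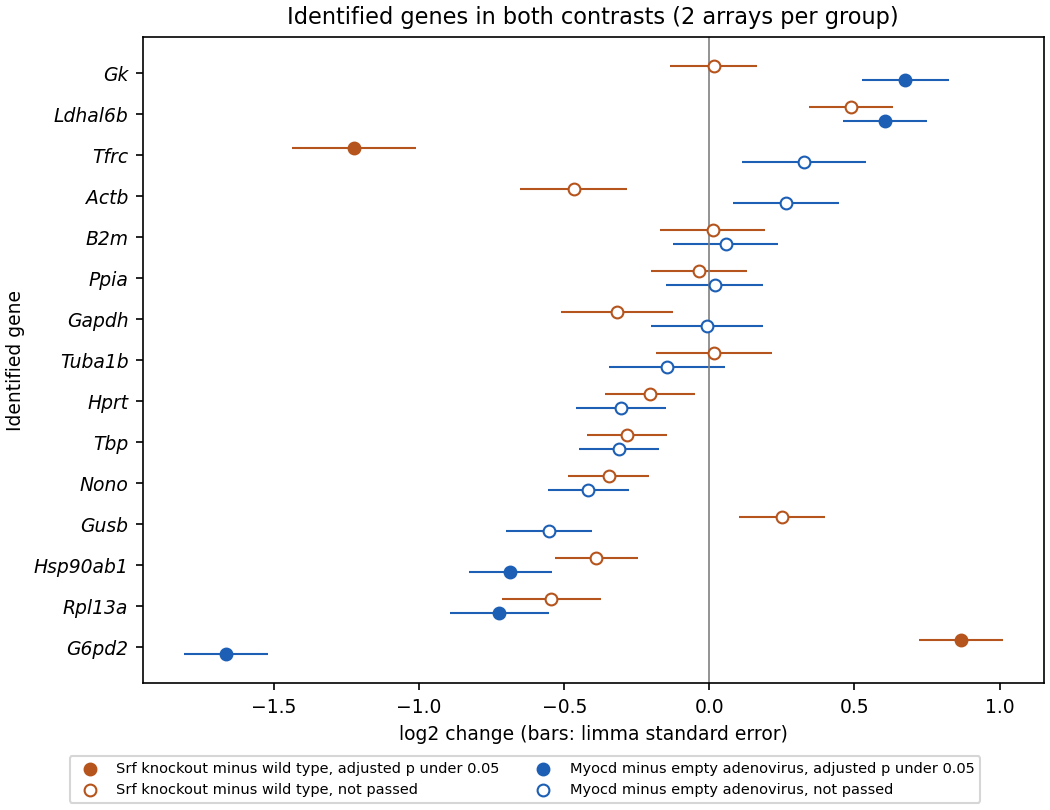
Log2 change of the 15 identified genes in Srf knockout against wild-type cells and in Myocd against empty adenovirus (x axis, log2 units; bars are limma standard errors; 2 arrays per group), with filled points for adjusted p under 0.05. G6pd2 lies at 0.87 in the knockout and at -1.67 with Myocd, and Tfrc at -1.22 and 0.33.

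Myocd adenovirus changed 6695 of 44081 tested probes (15.2%, limma), 3523 higher and 3172 lower. Which direction had more probes depended on the scaling, with 3580 higher and 3802 lower under quantile normalization and 3401 and 3751 with the authors' log2 values. At least 4-fold were 829 rises and 182 falls. The largest rises measured in both groups were those of ASMM10P026145, by 10.99 on the log2 scale (SE 0.18, limma adjusted p = 2.5e-05), and ASMM10P014268, by 9.53 (SE 0.13, limma adjusted p = 1.9e-05). Among the largest falls were those of ASMM10P041157, at -5.05 (SE 0.51, limma adjusted p = 0.0027), and ASMM10P041159, at -6.43 (SE 1.04, limma adjusted p = 0.0127). ASMM10P041159 was well above background on only 1 of the 2 Myocd arrays, so its size is not exact, and normexp gave -3.79 for it and -3.92 for ASMM10P041157. Among rises, 472 were not well above background on either wild-type array, with bounds of up to at least 936-fold, and among falls, 333 were not well above background on either Myocd array, with bounds of up to at least 10.2-fold. Of the humanlincRNA probes, 20 rose and 3 fell, against 33.2 and 23.4 in level-matched lists (permutation test, adjusted p = 0.0360 and 0.00107). Of the mouselincRNA probes, 17 rose and 5 fell, against 23.6 and 15.6 (permutation test, adjusted p = 0.208 and 0.0064). Permutation p-values here too leave out correlation between probes. ASMM10UP probes, with 21 rising and 16 falling, stood against 29.4 and 22.8 (permutation test, adjusted p = 0.202 and 0.208), and MM9LINCRNAEXON probes, with 3 and 0, against 3.62 and 2.66 (permutation test, adjusted p = 1 and 0.202). None of the 4 classes passed camera with Myocd (lowest limma adjusted p = 0.191), although with the preset correlation humanlincRNA passed without Myocd replicate 1 (limma adjusted p = 0.0257). On all arrays its limma adjusted p was 0.639 with an estimated correlation and 0.186 with fry. Under quantile normalization 17 humanlincRNA probes rose and 8 fell, and with the authors' log2 values 12 rose and 9 fell, so their number of falls depended on the scaling. The number of mouselincRNA calls was 10 with normexp, against 22. Array weights gave 12 humanlincRNA and 13 mouselincRNA calls, and probes well above background on all 6 arrays gave 14 and 7. The 23 humanlincRNA calls became 13 without either knockout array, 40 and 42 without wild-type replicates 1 and 2, and 15 and 7 without Myocd replicates 1 and 2. The 22 mouselincRNA calls became 35 without wild-type replicate 2 and 12 without Myocd replicate 2, and the 37 ASMM10UP calls 18 without either knockout array, 61 without wild-type replicate 2, and 16 and 11 without Myocd replicates 1 and 2. The count of all calls was 3906 without either knockout array, 2549 without Myocd replicate 1 and 2155 without Myocd replicate 2. The Myocd arrays lay on another slide than the wild-type arrays, so slide is confounded with Myocd in this contrast.

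Between the 2 effects, the direct contrast of Myocd with knockout cells called 12331 probes (limma), 5177 higher and 7154 lower with Myocd. Actb was 0.73 higher on the log2 scale with Myocd than in knockout cells (SE 0.18, limma adjusted p = 0.0306), and Tfrc 1.55 higher (SE 0.21, limma adjusted p = 0.00342). Gk was 0.66 higher (SE 0.15, limma adjusted p = 0.0214), Gusb -0.80 (SE 0.15, limma adjusted p = 0.0104) and G6pd2 -2.53 (SE 0.14, limma adjusted p = 0.000126). Tfrc and G6pd2 passed without any single array. Actb was lost without knockout replicate 1 or 2 (limma adjusted p = 0.106 and 0.166) and without Myocd replicate 1 or 2 (limma adjusted p = 0.127 and 0.129), and passed in 8 of 14 alternatives, with log2 changes from 0.64 to 0.82. Gk was lost without the same 4 arrays (limma adjusted p = 0.0918, 0.142, 0.0946 and 0.123), and Gusb without knockout replicate 1 or 2 or Myocd replicate 2 (limma adjusted p = 0.0919, 0.0532 and 0.0817). Over all alternatives, Gk stayed between 0.45 and 0.74 and Gusb between -0.90 and -0.71. The fits without either wild-type array are the same fit for this contrast, so the alternatives count it more than once. The count of probes was 5957 and 6810 without knockout replicates 1 and 2, and 7535 and 6564 without Myocd replicates 1 and 2. This contrast too lay across slides.

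Probes that fell in the knockout and rose with Myocd numbered 573, against 296 for independent lists of the same sizes. The largest changes in this class were those of ASMM10P000157, at -6.30 (SE 0.16) in the knockout and 6.21 (SE 0.16) with Myocd, and ASMM10P005241, at -4.88 (SE 0.18) and 5.06 (SE 0.18). In the opposite class, 585 probes rose in the knockout and fell with Myocd, against 388 for independent lists. ASMM10P014064 rose by 5.26 (SE 0.15) in the knockout and stood at -2.85 (SE 0.15) with Myocd. Probes higher in both numbered 928 against 431, and those lower in both 783 against 266. Simulated unchanged groups that share the wild-type arrays gave on average at most 0.01 probes in any class. Almost no probe passes in such groups, so this number does not measure what shared controls add among changed probes. The log2 changes of both contrasts correlated across probes with r = 0.14, where simulated unchanged groups gave 0.50, and probes are not independent replicates. Their covariance was 0.0859 against a simulated 0.0296, a difference of 0.0562. The simulation gave all groups the same spread, although the robust SD between replicates was 0.40 for wild-type and 0.20 for the other groups. The simulated 0.50 and 0.0296 are therefore likely too low for shared wild-type arrays, and the difference of 0.0562 too large. The wild-type arrays were too few to give each contrast its own replicated controls, so part of the excess over independent lists in the 2 classes of the same direction may come from the shared controls. Shared controls push both changes the same way, so they would lower the 2 opposite classes. Yet every class exceeded independent lists, with ratios of 1.94 and 1.51 for the opposite classes and 2.15 and 2.94 for the others. Both contrasts also use the same estimate of spread for each probe, which makes calls coincide in any direction. Independent lists leave this out, so 573 against 296 does not by itself show opposite effects of Srf loss and Myocd. The count of 573 became 215 and 266 without knockout replicates 1 and 2, and 248 and 234 without Myocd replicates 1 and 2.

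**Figure D2:**
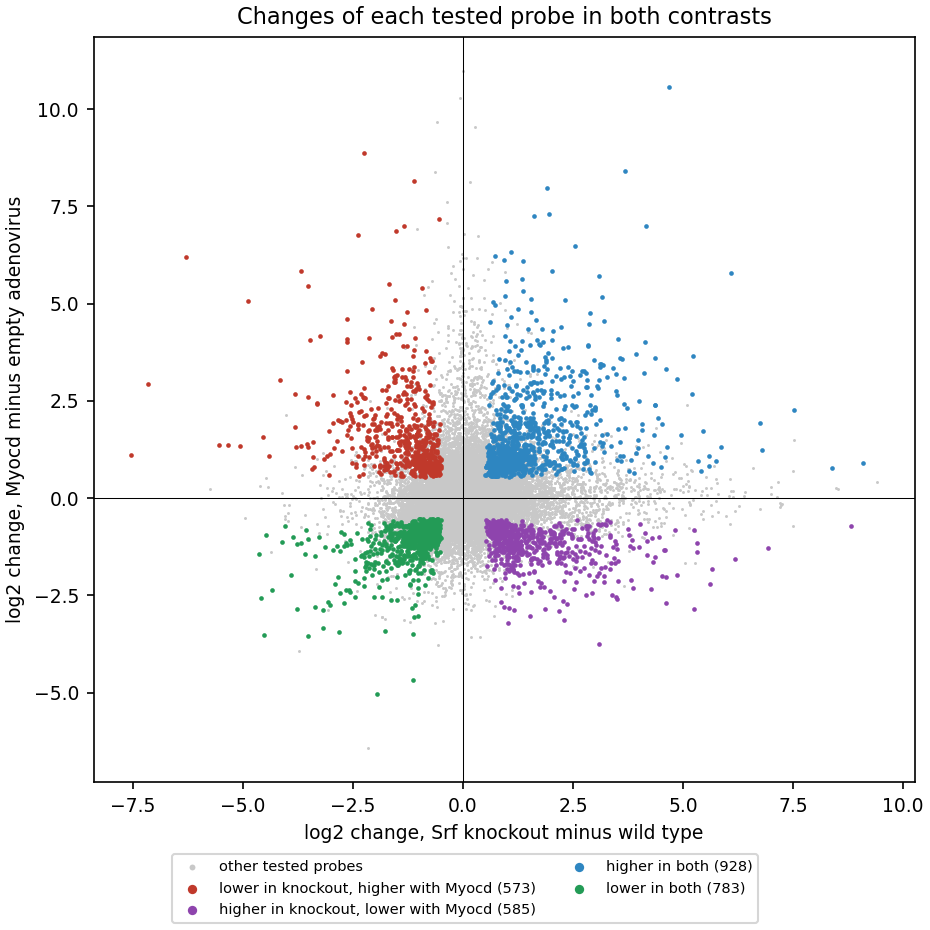
Log2 change of each tested probe in Srf knockout against wild-type cells (x axis) and in Myocd against empty adenovirus (y axis), both in log2 units from 2 arrays per group. Coloured points passed in both contrasts, 573 lower in the knockout and higher with Myocd, 585 the opposite, 928 higher in both and 783 lower in both.

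Aorta and liver, with 1 array each and no test, differed by at least 4-fold at 11561 probes, of which 5561 were higher in aorta and 6000 in liver. The median difference over the 34728 probes measured in both was -0.63, and quantile normalization moved it to -0.45. With quantile normalization, 6558 probes were higher in aorta and 5894 in liver, and with the authors' log2 values 6275 and 4784. Normexp gave 5695 probes, 3122 higher in aorta and 2573 in liver, so both the number and which tissue had more depended on the processing. On the liver array the log2 ratio of 5′ to 3′ control spots was -1.88 for Gapdh, against 0.29 to 0.64 on the cultured arrays and 0.36 in aorta, and at most -11.22 for Pgk1, against -3.91 to -3.05 and -4.60. Among identified genes, the TATA-binding protein gene Tbp was 3.46 log2 units higher in aorta, G6pd2 3.25 and Hsp90ab1 2.59, while B2m lay at -2.11, or at -0.59 with quantile normalization. Rpl13a lay at -0.40, and Actb at 1.09. Quantile normalization gave 3.99 for Tbp, 3.71 for G6pd2, 2.89 for Hsp90ab1, -0.022 for Rpl13a and 1.96 for Actb. The probe ASMM10P005241, lower in the knockout and higher with Myocd, was 946-fold higher in aorta than in liver. ASMM10P000157, with the largest change in that class, stood at -1.48 in aorta and 1.82 in wild-type cells. It was not well above background in liver. Of the 573 probes that fell in the knockout and rose with Myocd, 38.9% were at least 4-fold higher in aorta than in liver and 4.89% at least 4-fold lower, against 12.2% and 10.6% of all tested probes. Their median aorta minus liver difference was 1.53, above that of all 10000 level-matched random lists, which had a median of -0.22. The 585 probes of the opposite class had a median of 0.65, and 29.6% were at least 4-fold higher in aorta. The 3700 probes lower in the knockout had a median of 0.99 and the 5392 higher ones 0.04, against -0.24 and -0.41 in matched lists. With Myocd, the higher probes had a median of 0.09 and the lower ones 0.57, against -0.39 and -0.28. All 6 lists lay above all of their matched lists, those of opposite direction included, so this position is not particular to the 573 probes. The matched lists draw probes as independent units, and the matched level was a mean over all arrays, both tissues included. Against cultured wild-type cells, the median in aorta was -0.82 for the 573 probes and 0.46 for the opposite class. It was -1.75 for probes lower and 1.21 for probes higher in the knockout, and 0.57 for probes higher and -0.94 for probes lower with Myocd. These medians use the wild-type arrays that also define the lists, and aorta lay on another slide. Conversely, the probes at least 4-fold higher in aorta had, as a set, a median log2 change of -0.15 but a mean of 0.04 in the knockout, with a downward call by camera (limma adjusted p = 0.045) that was lost with an estimated correlation (limma adjusted p = 0.639) and with fry (limma adjusted p = 0.976). That call was also lost with quantile normalization (limma adjusted p = 0.548), without wild-type replicate 1 (limma adjusted p = 0.275), without knockout replicate 2 (limma adjusted p = 0.128), with the authors' log2 values (limma adjusted p = 0.491), with no filter on dim probes (limma adjusted p = 0.0624) and with centring on bright probes (limma adjusted p = 0.0522), and it passed in 7 of 14 alternatives. Of these 5370 probes, 931 rose and 988 fell. The set did not pass with Myocd (limma adjusted p = 0.419), and the set higher in liver passed in neither contrast (limma adjusted p = 0.191 and 0.583), although with the preset correlation it passed in the knockout without wild-type replicate 2 (limma adjusted p = 0.0113). With an estimated correlation, run on all arrays only, its adjusted p in the knockout was 0.821 (limma).

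**Figure D3:**
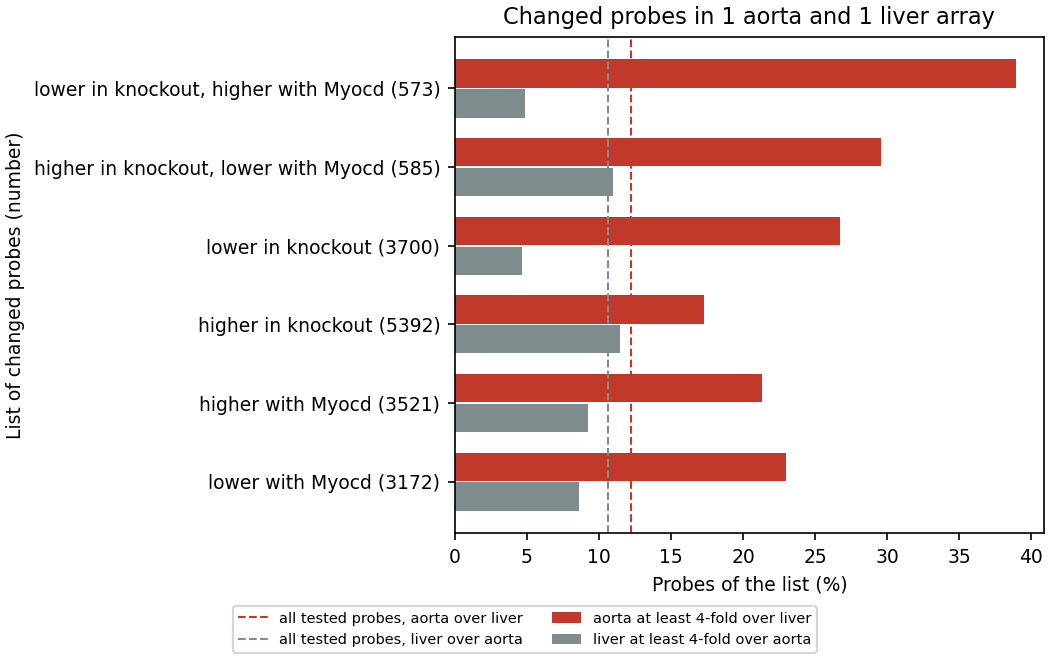
Share of each list of changed probes (x axis, percent) at least 4-fold higher in aorta than in liver or at least 4-fold higher in liver, from 1 array per tissue, with dashed lines for all tested probes at 12.2% and 10.6%. Probes lower in the knockout and higher with Myocd stand at 38.9% and 4.89%.

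Against cultured wild-type cells, whole aorta differed by at least 4-fold at 8514 probes, 4770 higher and 3744 lower in aorta, while the authors' log2 values gave 3435 higher and 4073 lower. Normexp gave 4995 probes, 2529 higher and 2466 lower. The median difference was 0.17, and -0.04 with quantile normalization. Gk was 2.83 log2 units higher in aorta than in the cells, whereas Rpl13a lay at -2.88, Nono at -2.29, Tfrc at -2.20, Tuba1b at -1.94 and G6pd2 at -1.89. Actb stood at -0.76. Quantile normalization gave 2.73 for Gk, -2.59 for Rpl13a, -2.03 for Nono, -1.93 for Tfrc, -1.65 for Tuba1b, -1.65 for G6pd2 and -0.43 for Actb. The single aorta array and the cells lay on different slides, so tissue and slide cannot be told apart here.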

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

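The control spots below are listed because their signal exceeded the brighter wild-type array at least 2-fold on every array of a group. Except for the MM9NEGATIVE probes, they were not part of any comparison. The 15 MM9NEGATIVE probes counted among the probes outside the control classes, and 1 of them was tested and called in neither contrast. Tests on the E1A spots and on the 5′ and 3′ spots were chosen after the values were seen.

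In aorta, the 35 spots of the control E1A_r60_a107, one of Agilent's adenoviral E1A-derived spike-in probes, had a median signal of 364, which was 107.2 times the brighter wild-type array, while all other arrays lay between 3.11 and 3.91. A carry-over of the spike-in mix would raise the other E1A spots too, and 0 of the other 9 E1A spot types were at least 2-fold above the brightest cultured array. Dust or damage on part of the array is also argued against, because the dimmest of the aorta spots was 31.2 times the brightest such spot on any other array. A transcript of aorta that hybridises to this probe, or a contaminant with that sequence alone, stays open and was not tested. The design names tissue as a difference between these arrays.

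The remaining control spots are given as values. On both Myocd arrays, DCP_20_7 was at least 3.09 times and DCP_20_9 at least 2.71 times the brighter wild-type array, with 2 spots each. ERCC-00097_63 was 2.18 times the wild-type value in aorta. In liver, E1A_r60_3 was 2.81 times and MM9NEGATIVE012 2.22 times the wild-type value.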

How the results depend on the processing

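Array weights, the crossed replicate block, the tests of sets and of identifier classes were chosen after the data were seen. Signal over background limits dim probes, since 62.2% (liver) to 74.7% of probes were well above it. The counts of the knockout contrast stayed within 1.5 times of 9096 under all alternatives except the added 2-fold threshold and the fits without a knockout array. With no filter on dim probes the Myocd count was 4211 and that of probes lower in the knockout and higher with Myocd 338, where more probes were tested. With only the 2 groups compared the Myocd count was 3906, from fewer arrays. A threshold of 2-fold in addition left 4916 knockout, 3741 Myocd and 7102 direct-contrast calls and 284 in the shared class, by construction. Normexp gave 5695 probes for aorta against liver and 4995 for aorta against wild-type cells. Its offset of 50, added before the log2 step, shrinks fold differences of dim probes by construction. How much of the lower counts comes from the offset was not tested. Leave-one-out ranges were 2701 to 13176 for the knockout, 2155 to 9213 for Myocd, 5957 to 16176 for the direct contrast, 215 to 598 for the shared class and 8195 to 9071 for aorta against wild-type cells. Fits with a lone array assume that it varies like the other groups.

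With the replicate number as a block, calls were 6380 for the knockout, 4394 for Myocd, 10062 for the direct contrast and 369 for the shared class, and the humanlincRNA set passed in the knockout by camera with the preset correlation (adjusted p = 0.0294). Without the block it did not pass with an estimated correlation (adjusted p = 0.639) or fry (adjusted p = 0.0916), and neither was run with the block. Differences between replicates 1 and 2 correlated across probes with r = -0.36 between wild-type and knockout. The values were -0.09 between wild-type and Myocd and 0.14 between knockout and Myocd, so the replicate number was not a consistent pairing. The value of -0.36 shows variation shared by wild-type replicate 1 and knockout replicate 2. Their 75th percentiles were 494 and 498, against 455 for wild-type replicate 2 and 452 for knockout replicate 1. The source of this variation was not tested. A block with the knockout numbers crossed gave 8240 knockout calls. With array weights there were 6404 knockout, 4615 Myocd and 17449 direct-contrast calls and 396 in the shared class. The weights were 0.44 for wild-type, 1.49 for knockout and 1.52 for Myocd arrays. The main fit assumes the same spread in all groups, although the robust SD between replicates was 0.40 for wild-type and 0.20 for the others. It may therefore understate the error of contrasts against wild type and overstate that of the direct contrast.

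Signs changed for values near 0. In the knockout contrast, quantile normalization gave 0.012 for Ppia and -0.12 for Gk. Centring on bright probes gave -0.030 for Tuba1b, -0.031 for Gk and -0.033 for B2m. Normexp gave 0.047 for ASMM10P026145. In the Myocd contrast, quantile normalization gave 0.019 for Tuba1b and 0.12 for Gapdh. Without single arrays, knockout values ranged from -0.21 to 0.19 for ASMM10P026145, -0.14 to 0.16 for B2m, -0.077 to 0.11 for Gk, -0.20 to 0.13 for Ppia and -0.25 to 0.28 for Tuba1b. Myocd values ranged from -0.090 to 0.20 for B2m, -0.24 to 0.23 for Gapdh, -0.15 to 0.18 for Ppia and -0.41 to 0.11 for Tuba1b. The set higher in liver turned downward with Myocd under no filter (adjusted p = 0.855), and its adjusted p ranged from 0.0604 to 0.934 without single arrays, and from 0.0113 to 0.913 in the knockout. The same ranges were 0.0604 to 0.897 for the set higher in aorta with Myocd and 0.684 to 0.975 for ASMM10UP in the knockout. The cause was not tested. A tally covered values for single genes, probes and sets, counts of calls in identifier classes and tissue medians of lists, those above included. Of these, 686 kept their side of the threshold or moved little, 36 lost and 12 gained a call, 67 moved and 9 changed sign. Without single arrays these numbers were 361, 45, 11, 24 and 21. Quantile normalization shifted the median knockout change of all probes from 0.07 to -0.03. Slide as a block, 1 probe per gene and the gene list tests were not run, since slide coincides with Myocd and few probes carry a gene name.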

Other observations

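The tests on the 5′ and 3′ spots were chosen after the values were seen, whereas the slide tests were fixed before their values were computed. Their random lists first left out called probes and were then drawn from all tested probes, which changed no outcome. Values of whole arrays place the tissues relative to the cells. Across probes well above background on all cultured arrays, aorta correlated with knockout cells at 0.89 and 0.88. It correlated with wild-type cells at 0.84 and 0.86 and with Myocd cells at 0.86 and 0.85. Liver correlated with knockout cells at 0.69 and 0.67, with wild-type cells at 0.61 and 0.65 and with Myocd cells at 0.64 and 0.64. The knockout arrays thus gave the highest values for both tissues, so this was not particular to aorta. These correlations are across probes, which are not independent replicates, and their differences were not tested. ASMM10P026145, the largest rise with Myocd measured in both groups, stood at 8.50 in Myocd cells, -2.49 in wild-type cells, -2.50 in knockout cells and -3.81 in aorta. In aorta ASMM10P006969, one of the largest falls in the knockout, stood at 5.21, and it was not well above background in liver.

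The glycolytic genes Gapdh and Pgk1 had control spots for both transcript ends, with 10 spots per end. The log2 ratio of 5′ to 3′ signal of Pgk1 was -3.91 to -3.05 on the 6 cultured arrays, -4.60 in aorta and -11.22 in liver. For Gapdh it was 0.29 to 0.64, 0.36 and -1.88. The Pgk1 5′ signal in liver was 8.06, near the 3.21 of the negative controls, so its ratio is only an upper bound. The liver ratio lay below all cultured arrays, by over 3 SD, for 2 of 2 genes. A loss of 5′ ends of the RNA or of its labelled copy would give this. The dim 5′ spots of the same genes prompted this test, so its outcome adds no separate support. Dimness of the liver array alone is argued against, because the Gapdh 5′ spots, far above background, changed by -2.30 log2 units relative to its 3′ spots between wild-type cells and liver. The same value for Pgk1, -7.92, is limited by the background. Other transcript ends in liver stay open and were not tested, and aorta against liver values may therefore depend on where a probe lies in its transcript.

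The Myocd arrays lay on slide 2 with both tissues, so a slide effect would move the changed probes in the tissues as well. For 827 rises of at least 4-fold (median 2.91), the smaller of the 2 tissue excesses over probes of the same wild-type level was -0.30, in liver, and the other, in aorta, was 0.68 (interval over random lists 0.61 to 0.77). Both lay below 1.45, the bound fixed for this test, which argues against slide as the source of the whole of these rises as a set. This holds only if these transcripts are not scarcer in both tissues than probes of the same wild-type level, which would mask a slide effect. The aorta excess lay in the direction of the rise, so a part from slide is not excluded. For 182 falls of at least 4-fold (median size 2.40), the smaller tissue excess was 2.10 in the direction of the fall, in aorta. The other was 2.44, in liver. A slide effect would give this, so slide remains a candidate explanation for these falls. Both differences use the same wild-type arrays, and a transcript abundant only in cultured wild-type cells would give the same pattern, so this does not exclude an effect of Myocd. For 2948 calls under 2-fold, the value was 0.42, in aorta, with an interval that includes 0.39, the bound fixed for this test, and 0.64 in liver, and slide and Myocd cannot be told apart for them.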
